A study of Danio rerio with 186 samples.

How the data were processed

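The study measured gene expression in single cells of the zebrafish pancreas. Per the labels' protocols, tissue from fish at 30 days post fertilization was dissociated with enzymes, cells were sorted by fluorescence directly into lysis buffer, and cDNA was made with Smart-Seq2 and sequenced on an Illumina NextSeq 500. Per the submitters' processing notes, reads were trimmed with Trim Galore, aligned across splice sites to the GRCz11 assembly with HISAT2 and assigned to exons with featureCounts. The versions of these tools, the annotation release, the handling of doublets in the sort and the strand setting are not given in the sources used here.

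The authors deposited 1 table of raw counts, with no normalization, in which each column is a cell. It holds 32046 rows: 31953 genes, 92 spike-in RNAs and 1 row named EGFP. Each column was matched to a cell through the library name in the sample description, and no column was without a sample. Spike-in rows took 5.61% of all reads and were kept out of the totals. The EGFP row counted in the totals and was left out of rankings. A row named AC024175.4 took a median of 9.02 to 11.0% of the reads per cell in the 4 pools, and what it represents is not given in the table; it was kept in the totals and left out of rankings because its name is not a gene symbol.

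Gate and plate came from the sample titles, which carry the gate, a number of 3 or 4 and a position on a grid of 8 rows and 12 columns. Reading the number as a plate is an interpretation of the titles. No animals are named, so each gate on each plate was treated as 1 sample, its kept cells were summed, and no p-value or standard error was computed. No 2 cells held identical counts. Cells with fewer than 500 detected genes or 50000 gene reads were left out: 1 of 33, 3 of 60, 3 of 27 and 5 of 66 cells in the ins+ pool of plate 3, the sst1.1+ ins+ pool, the ins+ pool of plate 4 and the sst1.1+ pool. Wells were filled by single-cell sorting, and no doublet caller was run.

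Levels are CPM of summed counts with exact Poisson intervals, and ratios carry the exact conditional binomial interval of a pair of Poisson counts. Shares of cells count cells with at least 5 reads, or a stated percentage of reads, with Clopper-Pearson intervals at 95%. All these intervals cover counting error only. A gene with 0 reads in a pool was set against a floor of 3 reads over the pool. Log2 ratios in rankings and lists add 1 CPM to both pools, which understates the change of low genes. For depth comparisons each cell was thinned without replacement to 100000 gene reads.

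Named genes were chosen by a rule fixed, like all gene lists and most alternatives, before the data were examined. The rule takes the 10 highest and 10 lowest genes with a symbol, hormones left out, among those with at least 50 CPM in the higher pool, at least 5 reads in 50% or more of its cells, a log2 ratio within 1 between the ins+ pools and the same direction in the mean over cells. Across plates, genes were ranked by the smaller of the direct ratio and the ratio relative to each plate's ins+ pool. Members of the fixed lists are named as examples. The signature lists are the first 50 genes of each direction on plate 4 by the same rule. The 11 fixed lists cover hormones, islet transcription factors, beta-cell function, delta-cell markers, granule and hormone processing, ER stress and protein folding, oxidative phosphorylation and the TCA cycle, glycolysis and lactate handling, the cell cycle, immediate-early and dissociation stress, and ribosomal proteins; hormones are reported gene by gene. Another 11 lists hold markers of cell types. Of 332 listed symbols, 296 matched the table directly, 20 through the gene ID in a table of gene names and 1 without regard to case, and 15 were not found. A list median counts members with at least 10 CPM in either pool. Its percentile is taken among 10000 random lists of the same size matched on mean expression, which describes these libraries and is not a test.

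The steps were tested on simulated Poisson counts drawn around the mean level of each pair of pools, with 100 genes raised and 100 lowered 4-fold. For sst1.1+ against ins+ cells, 94.8% of the intervals of 6374 genes held the true ratio. For sst1.1+ ins+ against ins+ cells, 95.7% of those of 5827 genes did. All changed genes were ranked first in both. The simulated counts follow the same Poisson model as the intervals, so this checks the code only. Differences between cells of a pool were not simulated, so it does not show how intervals or rankings behave in these pools. Alternatives were another total (without hormones), TMM factors from edgeR 4.0.16 in R 4.3.3, other cell filters, means over cells of CPM or log2 levels, the ins+ cells of both plates together, leaving out cells with over 5% of reads in gcga, gcgb, sst2, sst1.2 and ghrl, a pseudocount of 5 CPM, a minimum of 10 CPM, lists of 20 genes, shares from 1 read and shares after thinning. With the ins+ cells of both plates together, the filter for a log2 ratio within 1 between the ins+ pools was dropped from rankings. Further alternatives, chosen after seeing the data, kept the sst1.1+ ins+ cells at or below their median of gene reads per spike-in read or left out the cell with most gip reads. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. No genome was used here, so no coordinates are given.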

Results

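Single pancreatic endocrine cells of zebrafish at 30 days post fertilization were profiled by Smart-Seq2, a plate-based method that reads whole transcripts. The fish carried a transgene driven by the insulin promoter and a second one that puts membrane-bound EGFP under control of sst1.1, a somatostatin gene of delta cells. The sort gave 3 gates: 60 ins+ cells, 66 sst1.1+ cells and 60 sst1.1+ ins+ cells. The sample titles carry a number, 3 or 4, followed by a well-like position, which is read here as the plate. All sst1.1+ ins+ cells came from plate 3 and all sst1.1+ cells from plate 4, while the ins+ cells were split between both plates, with 33 on plate 3 and 27 on plate 4. Within each plate the gates filled different rows, apart from row F of plate 3 and row C of plate 4. Differences between gates of a plate therefore cannot be told apart from effects of the row. The count table held 1745 to 895868 gene reads per cell, and 174 of the 186 cells passed a filter of 500 detected genes and 50000 gene reads.

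Kept cells were summed into 4 pools, since no animals are named and cells of 1 sort are not replicates. The ins+ pool of plate 3 had 32 cells and 13530311 gene reads, the sst1.1+ ins+ pool had 57 cells and 27382339 reads, the ins+ pool of plate 4 had 24 cells and 12550652 reads, and the sst1.1+ pool had 61 cells and 34186971 reads. Median gene reads per cell were 422832, 484520, 536886 and 556705 in that order. With 1 pool per gate and plate, no difference has a replicate check and no test was made. Levels are CPM, the reads of a gene scaled by 1e6 over the summed gene reads of a pool or cell, and 95% intervals in brackets cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

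The ins+ gate, sorted on both plates, is the only repeat in the design. The ins+ pools had similar levels of ins and of the beta-cell genes pdx1 and gck: ins stood at 368884 CPM on plate 4 and 397976 on plate 3, the homeobox factor pdx1 at 1438 and 1358, and the glucose sensor gck at 729 and 647. Other hormones differed between them: sst1.1 stood at 9410.5 CPM on plate 4 and 1389 on plate 3, sst1.2 at 554 and 8582, sst2 at 14.9 and 5281, the glucagon genes gcga at 5711 and 2330 and gcgb at 2784 and 323. Single cells carried much of this: without the cell with most reads of the gene in each pool, sst1.1 stood at 793 and 596 CPM and gcga at 693 and 552 CPM on plates 4 and 3, and on plate 3 sst1.2 stood at 3523 and sst2 at 2427 CPM. Among beta-cell function genes abcc8 stood at 112 and 41.6 CPM and ucn3l at 12.8 and 28.01, with a list median of 0.17. Across 1735 genes with at least 50 CPM in either pool, log2 ratios of plate 4 to plate 3 had an SD of 0.75, equal to 1.68-fold, and 85.6% of genes lay within 2-fold. The cell cycle list differed most by its median, which was 1.71 higher in log2 on plate 4. That list holds few reads from few cells, with 69.7% of its reads on plate 3 and 71.8% on plate 4 coming from 3 cells.

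Hormone reads followed the sort in most cells. The median sst1.1+ cell held 255477 CPM of sst1.1 and 135 CPM of ins, and the median ins+ cell held 406364 CPM of ins on plate 3 and 375017 on plate 4, with 23.2 and 38.6 CPM of sst1.1. The median sst1.1+ ins+ cell held 202351 CPM of ins and 128368 CPM of sst1.1. In the sst1.1+ ins+ gate, 45 of 57 cells (78.9%; exact binomial interval 66.1 to 88.6%) had at least 5% of their reads in each of the hormones, against 0 of 32 and 1 of 24 ins+ cells and 0 of 61 sst1.1+ cells. Another 10 cells of this gate had ins at that level without sst1.1, and 2 had sst1.1 without ins. In the sst1.1+ gate 59 of 61 cells had sst1.1 at that level and 2 had neither hormone: 1 held 149563 CPM of gcga and 164575 CPM of gcgb, and 1 had 711 genes and 74.7% of its reads in the row AC024175.4. Both were kept in the pool. EGFP stood at 4020 CPM in the sst1.1+ pool and at 1590 CPM in the sst1.1+ ins+ pool. As ins and sst1.1 drive the reporters that set the gates, these values check the labels and are not findings.

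**Figure D1:**
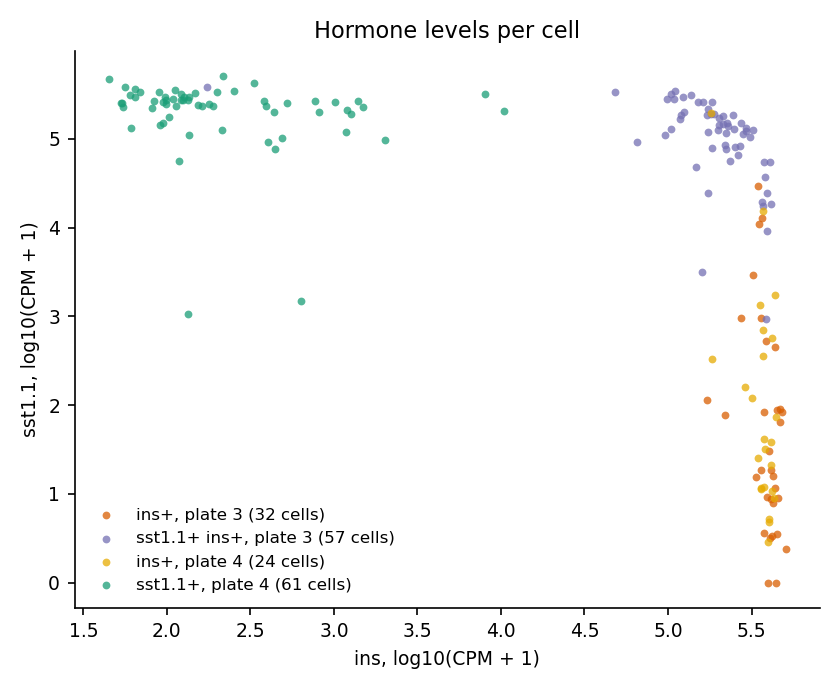
Levels of ins (horizontal) and sst1.1 (vertical) in each kept cell, as log10 of CPM plus 1, coloured by gate and plate. The sst1.1+ ins+ cells lie at the upper right, with medians of 202351 CPM of ins and 128368 CPM of sst1.1, and 10 of them have under 5% of their reads in sst1.1.

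Cells of the double gate also carried more genes. The sst1.1+ ins+ cells had a median of 4999 detected genes, against 2564 and 2746.5 in the ins+ cells of plates 3 and 4 and 3616 in the sst1.1+ cells. With each cell thinned to 100000 gene reads (1 sst1.1+ ins+ cell fell short and was left out), the medians were 4204, 2307.5, 2465.5 and 3167. The ratio of gene reads to spike-in reads, which rises with the amount of cellular RNA in the well, had medians of 71.1 in sst1.1+ ins+ cells, 28.3 and 29.1 in ins+ cells and 41.8 in sst1.1+ cells. As the gates filled different rows, uneven amounts of spike-in between rows would change this ratio as well.

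**Figure D2:**
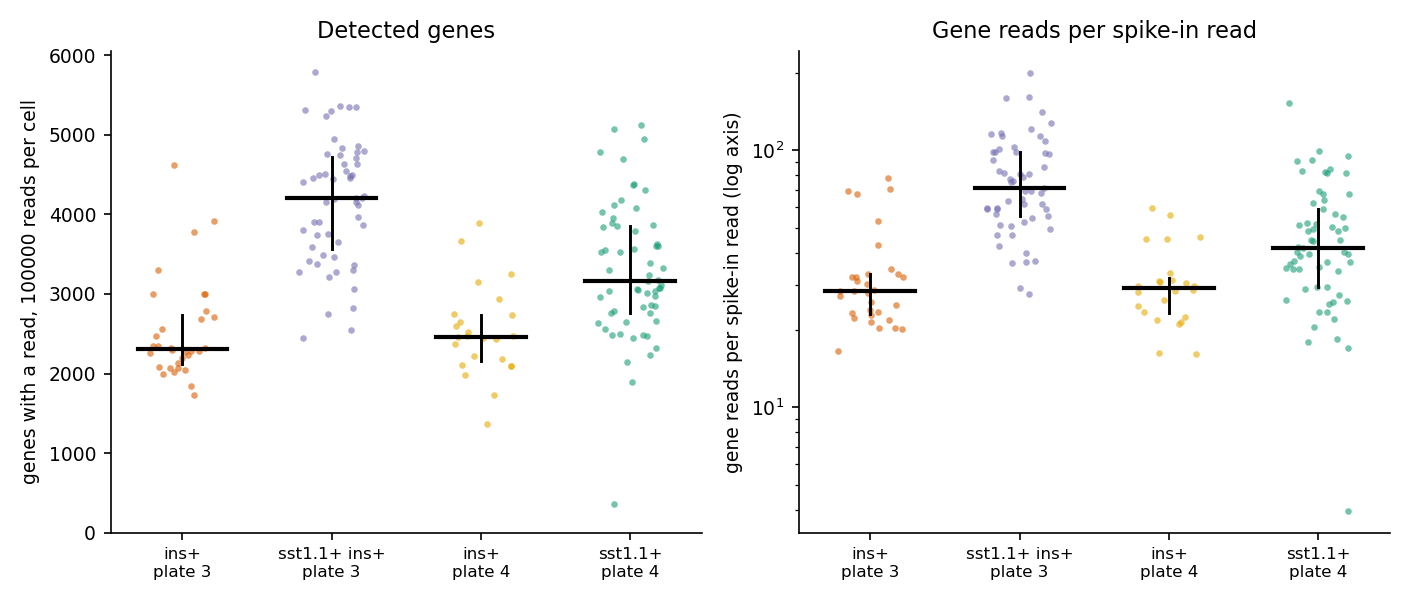
Left, genes with a read in each kept cell after thinning to 100000 gene reads; right, gene reads per spike-in read on a log axis. Points are cells, horizontal bars are medians and vertical bars span the quartiles; the sst1.1+ ins+ cells have the highest medians, 4204 genes and 71.1 gene reads per spike-in read.

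Which genes set sst1.1+ cells apart from ins+ cells was asked on plate 4, where both were sorted. The sst1.1+ pool had 5842 CPM of dkk3b (ENSDARG00000070683), a secreted protein of the dickkopf family, against 297 CPM in the ins+ pool, a ratio of 19.7 (19.04 to 20.3). The ETS factor elf3 (ENSDARG00000077982) stood at 225 CPM against 0 reads, 941-fold higher against a floor of 3 reads over the pool. Its interval reached down to 765-fold. HHEX, a homeobox factor of delta cells, was at 68.0 against 0.956 CPM, and the peptide hormone gene pyyb was 22.1-fold higher. In the other direction, the homeobox factor nkx6.2 (ENSDARG00000104735) stood at 92.7 CPM in ins+ cells and had 0 reads in the 61 sst1.1+ cells. That is 1056-fold lower against the same floor, which is not a lower bound. Gene mnx1, a homeobox factor of beta cells, was at 79.6 CPM in ins+ cells against 3.86 CPM.

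Chaperones and immediate-early genes filled most of the remaining top ranks of the sst1.1+ cells. The heat-shock genes hsp90aa1.2, hspa4a, DNAJA4 and hsp70.1 were 19.2-, 21.7-, 18.4- and 17.99-fold higher, and the transcription factor klf6a was 24.8-fold higher. The fixed list of immediate-early and dissociation stress genes had a median log2 ratio of 2.65 over 25 measured members, above all 10000 random lists matched on expression. Within it, jun stood at 1063 against 13.7 CPM and atf3 at 880 against 14.3 CPM. The list of ER stress and protein folding genes had a median of 1.103, again above all random lists, with the ER chaperone hspa5 at 2507 against 261 CPM and the stress factor ddit3 at 153 against 22.9 CPM. The natriuretic peptide receptor gene npr1a stood at 61.2 against 1.27 CPM. Gene fam46bb was 272-fold higher against the floor of 3 reads, with an interval that reached down to 221-fold. Reads of hsp70.1, hsp70.2, hsp70.3 and hsp70l, similar copies of 1 gene family, are uncertain between members.

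Among the genes lower in sst1.1+ cells, the glucagon receptor gene gcgra was at 0.176 against 73.6 CPM, the vesicle GTPase gene rab3c at 1.90 against 100.4 CPM, and the zinc finger factor insm1b had a ratio of 0.0798. Also among the 10 lowest were abhd15a, at 6.08 against 285 CPM, dgkaa, nell2a, rcan2 and sardh, with ratios from 0.0213 to 0.0844. The proprotein convertase gene pcsk1 had a ratio of 0.265 (0.258 to 0.271). Beta-cell genes went different ways: g6pcb had a ratio of 0.321 and ucn3l of 3.82, while pdx1, gck and the glucose transporter gene slc2a2 stood near parity, at 0.928, 1.22 and 1.11. The lists of islet transcription factors, beta-cell function, granule and hormone processing and ribosomal proteins had medians of −0.28, −0.40, −0.08 and −0.03, at percentiles 8.12, 5.17, 21.6 and 22.3 of random lists. These depend on the processing: beta-cell function turned to 0.028 with the ins+ cells of both plates and stood at −0.16 with means of log2 levels over cells, and a total without hormones gave −0.45, −0.57, −0.25 and −0.19 for these lists. Oxidative phosphorylation and the TCA cycle stood at 0.25, glycolysis and lactate handling at 0.49 (percentiles 97.5 and 97.1; 0.080 and 0.33 with a total without hormones), and the cell cycle at −1.23, less than the 1.71 by which the ins+ pools differed. The 5 measured delta-cell markers split, with HHEX, cdh10a and dkk3b higher and nkx6.2 and ptprz1b lower, so that the list median of 4.29 is the value of dkk3b.

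A single cell decided one ranked gene: gip, at 2894 CPM in the sst1.1+ pool, fell to 26.6 CPM without the 1 cell that held 99.1% of its reads, below the 30.3 CPM of ins+ cells. The ranking depends on several choices: of the 20 named genes, 6 stayed with means of log2 levels over cells in place of summed reads, 11 with the ins+ cells of both plates and 13 without cells over 5% other hormones. The 11 reflects the joined ins+ cells and the dropped filter between the ins+ pools together.

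The sst1.1+ ins+ cells were compared with ins+ cells on plate 3, where both were sorted. Gene dkk3b ranked first among the genes read in at least 50% of the sst1.1+ ins+ cells that met the rule for naming, with 2835 CPM in the sst1.1+ ins+ pool against 184 CPM in the ins+ pool, a ratio of 15.4 (14.8 to 16.1). The TALE homeobox factor pbx3b was 8.04-fold higher, the kinase gene mknk2b 7.54-fold, the amino acid transporter gene slc38a2 6.07-fold and the secreted glycoprotein gene mfge8b 5.51-fold higher. The chaperone genes hspa4a, hspbp1 and hsp90aa1.2 were 8.94-, 5.74- and 5.17-fold higher, and the immediate-early genes junbb and ier2 5.01- and 5.05-fold higher. HHEX was at 28.3 against 3.99 CPM and pyyb 8.05-fold higher.

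The same stress lists stood out. Immediate-early and dissociation stress genes had a median log2 ratio of 1.61 and ER stress and protein folding genes of 0.65, both above all 10000 random lists, while the ins+ pools differed by −0.01 and 0.15. Within them atf3 stood at 246 against 3.18 CPM, jun at 332 against 29.3 CPM, ddit3 at 94.2 against 29.05 CPM and hspa5 at 851 against 299 CPM. The list of granule and hormone processing genes had a median of −0.17 at percentile 10.3. Of its 22 measured members 2 were over 2-fold higher, 2 over 2-fold lower and 18 within 2-fold. The granin gene chga, over 2-fold higher, had a ratio of 2.56, and scg2b, within 2-fold, had a ratio of 1.90.

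The 10 named genes lower in sst1.1+ ins+ cells had ratios between 0.265 and 0.412: fbxo25, the histamine receptor gene HRH2, the fatty acid desaturase gene scdb, the adiponectin receptor gene adipor1b, snx9b, tagln3b, nell2a, pcsk1, slc38a11 and znf395b. The convertase gene pcsk1 (ENSDARG00000002600) stood at 380 CPM against 976 CPM, a ratio of 0.389 (0.379 to 0.399), near the 325 CPM of sst1.1+ cells. In contrast nkx6.2 and mnx1, nearly missing from sst1.1+ cells, were kept at 49.8 and 43.5 CPM against 86.4 and 80.04 CPM in ins+ cells. Lists of islet transcription factors and beta-cell function had medians of −0.60 and −0.46, at percentiles 0.32 and 1.95. The list medians were 0.04 for oxidative phosphorylation and the TCA cycle (−0.023 with a total without hormones), −0.10 for glycolysis and lactate handling and 0.11 for ribosomal proteins. Delta-cell markers split again, with HHEX, cdh10a and dkk3b higher and nkx6.2 and GABRG3 lower, and their median of 2.56 is the value of HHEX.

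Cell cycle genes had a median log2 ratio of 1.70, above all random lists but no larger than the 1.71 between the ins+ pools. The topoisomerase gene top2a stood at 50.3 CPM in the sst1.1+ ins+ pool and at 5.47, 35.4 and 11.1 CPM in the ins+ pools of plates 3 and 4 and the sst1.1+ pool. After thinning, 10 of 56 sst1.1+ ins+ cells (17.9%; interval 8.91 to 30.4%) had at least 10 members of the list with 5 reads or more, against 2 of 32, 3 of 24 and 5 of 61 in the other pools, so that intervals overlapped. Of the 20 named genes, 11 stayed with the ins+ cells of both plates, where the filter between the ins+ pools was dropped as well, and 14 without cells over 5% other hormones. With means of log2 levels over cells in place of summed reads 7 stayed, and the lists of islet transcription factors, beta-cell function, granule genes and glycolysis turned to 0.084, 0.26, 0.047 and 0.94, below the median of all genes on that scale, 1.01.

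**Figure D3:**
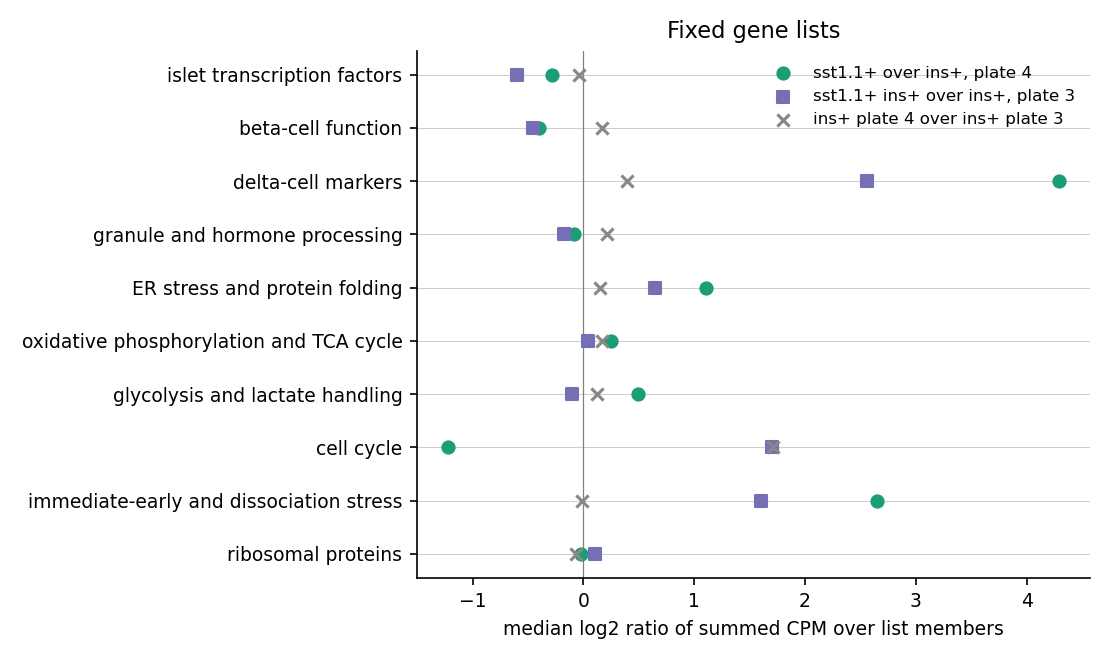
Median log2 ratio of summed CPM over the measured members of each fixed gene list. Circles compare sst1.1+ with ins+ cells on plate 4, squares sst1.1+ ins+ with ins+ cells on plate 3, and crosses the ins+ pools of the plates with each other; immediate-early and dissociation stress genes stand at 2.65, 1.61 and −0.01.

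Where the sst1.1+ ins+ cells fall between the single gates was measured with lists ranked on plate 4 and read on plate 3. The sst1.1+ ins+ cells had no part in the choice of genes, and the ins+ cells of plate 3 entered it only through the filter for a similar level in both ins+ pools. The 50 sst1.1-high genes, hormones left out, had a median log2 ratio of 2.95 between sst1.1+ and ins+ cells on plate 4. On plate 3 they stood 1.85 higher in sst1.1+ ins+ cells than in ins+ cells (quartiles 1.21 and 2.38), above all 10000 random lists. The 50 ins-high genes stood at −2.20 on plate 4 and at −0.86 on plate 3 (quartiles −1.03 and −0.65), below all random lists. Between the ins+ pools the lists differed by −0.19 and 0.26. Scored per cell as the mean log2 level of the sst1.1-high list minus that of the ins-high list, the median was −2.66 and −3.08 in ins+ cells of plates 3 and 4, 0.86 in sst1.1+ ins+ cells and 4.48 in sst1.1+ cells. The sst1.1-high list alone had medians of 2.43, 2.52, 6.03 and 6.71 in these groups of cells, in that order. The ins-high list alone had medians of 5.26, 5.68, 5.21 and 2.26. An intermediate score is thus not an intermediate level of each list. The cells of plate 4 chose the lists, which widens the distance between their own scores. The sst1.1-high list includes the chaperone genes hspa4a and hsp90aa1.2, the immediate-early list member klf6a, and gip, whose reads came mostly from a single cell. The fixed list of immediate-early and dissociation stress genes stood 1.61 higher on plate 3 as well. The score thus mixes stress genes with others and was not computed without them. With genes ranked anew on means of log2 levels over cells, the ins-high list stood at −0.054 on plate 3. The median of all genes rose to 1.01 on that scale.

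**Figure D4:**
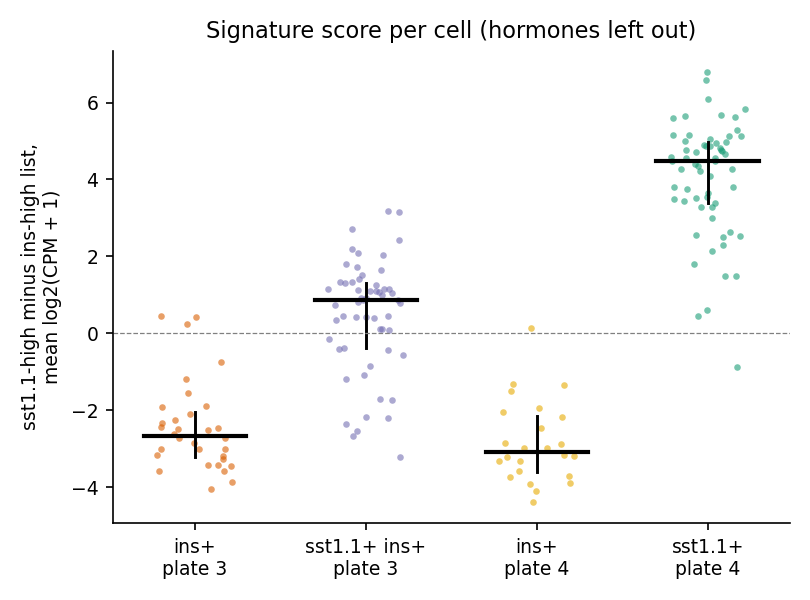
Score per kept cell, the mean log2(CPM + 1) of the 50 sst1.1-high genes minus that of the 50 ins-high genes, with hormones left out of both lists. The sst1.1-high list includes chaperone and immediate-early genes. Horizontal bars are medians and vertical bars span the quartiles. The score of the sst1.1+ ins+ cells, with a median of 0.86, lies between ins+ cells at −2.66 and −3.08 and sst1.1+ cells at 4.48. Their ins-high list alone had a median of 5.21, near the 5.26 of ins+ cells of plate 3.

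The sst1.1+ ins+ and sst1.1+ gates share no plate, so their direct ratio cannot be told apart from the plate, and genes are named only where the ratio relative to each plate's own ins+ pool had the same direction. Higher in sst1.1+ ins+ cells were abhd15a, at 136 against 6.08 CPM, rab3c, at 51.2 against 1.90 CPM, dgkaa, rcan2 and kalrnb, with ratios of 22.3, 26.9, 10.5, 6.58 and 6.21. The pyruvate carboxylase gene pcxb, ndufa4l2a, the chemokine gene cxcl14, cd164 and prkdc followed, with ratios between 3.01 and 4.72. Lower were elf3, at 61.1 against 225 CPM, the growth factor gene pdgfab, fam46bb, cd164l2, hspa5, ywhag2, hspbp1, DNAJA4 and sptlc2b, with ratios between 0.272 and 0.359. Also ranked there was gip, which the same single sst1.1+ cell decided.

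By list, sst1.1-high genes stood at −1.04 and ins-high genes at 1.19 in sst1.1+ ins+ against sst1.1+ cells. The ins-high value was 2.52 with lists ranked anew on means of log2 levels over cells, and 2.197 with lists of 20 genes. These lists were chosen as the extremes of the same sst1.1+ pool, so a shift toward the middle is built in and says little by itself. Immediate-early and dissociation stress genes had a median of −0.91 and ER stress and protein folding genes of −0.69, at percentiles 0 and 0.01, and −1.096 and −0.51 relative to each plate's ins+ pool. The lists of islet transcription factors and beta-cell function stood at −0.05 and −0.14, near zero and with a direction that changed with a total without hormones, TMM factors or means of log2 levels over cells. The cell cycle list went the other way from the stress lists, at 1.34 directly and 2.45 relative to each plate's ins+ pool, where the ins+ pools themselves differed by 1.71. Glycolysis and lactate handling stood at −0.48 directly and −0.53 relative to the ins+ pools, and turned to 0.058 and 0.32 with means of log2 levels over cells. Of the 20 named genes, 9 stayed with means of log2 levels over cells and 12 without cells over 5% other hormones.

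Alpha-cell markers reached 13244 CPM with gcga, and markers of sst2 or sst1.2 delta cells 23776 CPM with sst1.2, both in the sst1.1+ pool. Markers of non-endocrine cell types were lower. The highest summed levels of any endothelial, erythroid and hepatocyte marker were 2.02, 0.876 and 4.54 CPM in any pool, and those of acinar and fibroblast or mural markers were 48.2 and 25.8 CPM, both in the sst1.1+ pool. Leukocyte markers reached 136 CPM with cd74b in the ins+ pool of plate 4, neural or glial markers 114 CPM and duct or progenitor markers 314 CPM with krt8 in the sst1.1+ pool, a keratin gene. The ghrelin gene ghrl, the epsilon-cell marker, lay between 58.5 and 95.2 CPM in the 4 pools. In the left-out wells it ranged from 90020 to 123014 CPM, apart from a well without ghrl reads. The median kept cell held 82.2 CPM in the ins+ pool of plate 3. It held 33.6 CPM in the sst1.1+ ins+ pool, which had more gene reads per spike-in read. These levels cannot be told apart from a background that follows the spike-in reads. Left-out wells with ghrl reads also held ins, at 148424 to 179172 CPM, sst1.2, at 31493 to 90357 CPM, and sst2, at 22495 to 50236 CPM. The 135 CPM of ins in the median sst1.1+ cell shares this limit, as do low levels of sst1.2 and sst2, such as the 14.9 CPM of sst2 in the ins+ pool of plate 4.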

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

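The tests of this part were chosen after the result was seen. EGFP reads are outside the comparisons, and they were found in ins+ cells, which were sorted outside the sst1.1 gate: 300.4 CPM on plate 3 and 199 CPM on plate 4, above the 0.222 and 0.239 CPM that a count of 0 would allow. The median ins+ cell had 223 CPM of EGFP on plate 3 and 195 CPM on plate 4, against 3809 CPM in the median sst1.1+ cell, so the reads were spread over cells.

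RNA carried over from sst1.1+ cells is argued against by sst1.1, the most abundant transcript of those cells. Carry-over would bring both in proportion, but the median level in ins+ cells was 0.0133% of that in sst1.1+ cells for sst1.1 and 5.48% for EGFP. Another candidate explanation is that the EGFP row caught reads of the fluorescent proteins of the insulin transgene, a multicolour construct in the same fish, some of which share sequence with EGFP. The median EGFP level over ins+ cells was 209 CPM, which this explanation and weak activity of the sst1.1 reporter in ins+ cells cannot be told apart by; the sequences of the reads or of the reporters would decide. No biological explanation was tested.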

How the results depend on the processing

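Alternatives with the sst1.1+ ins+ cells of fewer reads per spike-in read and without the cell with most gip were chosen after the data were seen. The sst1.1-high and ins-high lists were ranked anew under each alternative, so their genes can differ from those of the main lists. Of 1234 alternative values of 127 results, 1050 moved by less than the spread between the ins+ pools or the counting interval, 173 moved further, and 11 turned from a value that lay beyond that spread. Counting also values that started within the spread of zero, 34 changed sign. Part of the 1050 could not move, because some alternatives changed no cell of the pools compared. Leaving out the cell with most gip, an sst1.1+ cell, cannot change gene or fixed-list ratios of sst1.1+ ins+ over ins+ cells. Choosing among the sst1.1+ ins+ cells cannot change those of sst1.1+ over ins+ cells. The count of 1050 therefore overstates how stable the results are. No ratio or median moved beyond the spread under the stricter cell filter or the mean of per-cell CPM (110 values each), nor did the 6 signature medians tried with a minimum of 10 CPM. The choice of named genes did change: the mean of per-cell CPM kept 18, 17 and 18 of 20 in the 3 comparisons, and the minimum of 10 CPM kept 20, 18 and 15.

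Averaging log2 levels over cells moved 63 values and turned 8, and 14 changed sign if values that started near zero are counted. It raised the median of all genes from 0.03 to 0.39 in sst1.1+ over ins+ cells, from −0.02 to 1.01 in sst1.1+ ins+ over ins+ cells and from −0.22 to 0.41 in sst1.1+ ins+ over sst1.1+ cells, and list values are to be read against these. For sst1.1+ ins+ over ins+ cells it gave 3.03 for sst1.1-high genes, −0.054 for ins-high genes, 10.91 for sst1.1, 0.084 for islet transcription factors, 0.26 for beta-cell function, 0.998 for delta-cell markers, 0.047 for granule genes, 2.03 for ER stress, 0.77 for oxidative phosphorylation, 0.94 for glycolysis and 2.24 for immediate-early genes. For sst1.1+ over ins+ cells it gave −10.71 for ins, 11.05 for sst1.1, −0.16 for beta-cell function, 1.482 for delta-cell markers, 1.87 for ER stress, 0.69 for oxidative phosphorylation, 0.72 for glycolysis and −0.11 for ribosomal proteins. For sst1.1+ ins+ over sst1.1+ cells it gave −1.23 for sst1.1-high genes, 2.52 for ins-high genes, 0.17 for granule genes, 0.15 for oxidative phosphorylation and 0.058 for glycolysis, with 0.10 and 0.32 for the last lists relative to the ins+ cells of each plate.

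A total without hormones moved the median of all genes from 0.03 to −0.14 in sst1.1+ over ins+ cells and from −0.22 to −0.05 in sst1.1+ ins+ over sst1.1+ cells. It gave, for sst1.1+ over ins+ cells, −0.45 for islet transcription factors, −0.57 for beta-cell function, −0.25 for granule genes, 0.94 for ER stress, 0.080 for oxidative phosphorylation, 0.33 for glycolysis, 2.49 for immediate-early genes and −0.19 for ribosomal proteins, with 0.042 for the last in sst1.1+ ins+ over ins+ cells. Against sst1.1+ cells it gave −0.88 for sst1.1-high and 1.44 for ins-high genes. TMM factors gave −0.87 for sst1.1-high genes against sst1.1+ cells and 0.16 for ribosomal proteins against ins+ cells, and moved the median of all genes against sst1.1+ cells to −0.04.

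With the ins+ cells of both plates, sst1.1 stood at 5.59 in sst1.1+ and 4.78 in sst1.1+ ins+ cells, because 1 ins+ cell of plate 4 held 91.95% of its pool's sst1.1 reads. Beta-cell function turned to 0.028 and immediate-early genes moved to 2.46 in sst1.1+ cells, and in sst1.1+ ins+ cells sst1.1-high genes stood at 2.51, beta-cell function at −0.61 and granule genes at −0.33.

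Without cells over 5% other hormones, sst1.1+ ins+ over ins+ cells gave 2.10 for sst1.1-high genes, 3.73 for delta-cell markers, 0.85 for ER stress and 2.07 for immediate-early genes. Over sst1.1+ cells they gave −1.22 for sst1.1-high and 1.43 for ins-high genes. In sst1.1+ over ins+ cells, ER stress stood at 1.28, immediate-early genes at 2.82 and gip at −0.11; without the cell with most gip, gip stood at −0.18.

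A pseudocount of 5 gave 2.39 for delta-cell markers and 2.45 for immediate-early genes in sst1.1+ over ins+ cells, and 2.02 for sst1.1-high genes, 1.69 for delta-cell markers and 1.38 for immediate-early genes in sst1.1+ ins+ over ins+ cells. Lists of 20 genes gave 2.44 for sst1.1-high genes against ins+ cells, and −1.25 and 2.197 for sst1.1-high and ins-high genes against sst1.1+ cells. With no cell filter ins-high genes stood at 0.95 against sst1.1+ cells. In the sst1.1+ ins+ cells with fewer reads per spike-in read, ins-high genes stood at 1.39 against sst1.1+ cells, and islet transcription factors at −0.38, ER stress at 0.79 and oxidative phosphorylation at 0.17 against ins+ cells. Cell cycle medians in both comparisons with ins+ cells moved by less than the spread under all alternatives run, as that spread, set by the ins+ pools, is wide. No paired analysis was possible because no animals or pairs are named.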

Other observations

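The test of wells with 2 cells and the test of sequencing depth were written before their results were seen; the shares of the other pools, the mixture, the simulated pairs and the tests of gcga in ins+ cells were chosen after. Some wells carried further hormones. Among 61 sst1.1+ cells, 8 (13.1%, exact binomial interval 5.84 to 24.2%) had at least 5% of their reads in each of sst1.1 and gcga, the glucagon gene. Another 3 had this in each of sst1.1 and sst2. These wells had 44.7 to 91.4 and 81.5 to 98.9 gene reads per spike-in read, against a median of 41.8 in the sst1.1+ pool. Whether they held 2 cells was not tested, so they cannot be read as single cells with several hormones. Of the sst1.1+ ins+ cells 2 of 57 paired sst1.1 with gcga, and in the ins+ gate 1 of 32 and 1 of 24 cells paired ins with gcga. Taking ins or sst1.1 together with gcga or sst2, the shares were 9.38% and 4.17% in ins+ cells of plates 3 and 4, 7.02% in sst1.1+ ins+ cells and 18.03% in sst1.1+ cells. The sibling gene sst1.2 was read in cells with at least 5% of their reads in sst1.1 and under 1% in sst2. It stood at a median of 4.66% of the sst1.1 level in 46 such sst1.1+ ins+ cells and at 4.78% in 52 sst1.1+ cells. This choice leaves out cells with much sst1.2, such as an sst1.1+ cell with 231800 CPM of it against 93147 CPM of sst1.1. Reads shared between these paralogs were not tested.

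A few cells of each gate carried cell cycle genes. The list summed to 1231 CPM in sst1.1+ ins+ cells, 506 and 1302 CPM in the ins+ cells of plates 3 and 4 and 588 CPM in sst1.1+ cells. The 3 cells with most of these reads held 35.2% of them in the sst1.1+ ins+ pool and 69.7, 71.8 and 44.5% in the others, in pools of different size.

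The sst1.1+ ins+ cells carried both hormones, more genes and more RNA per spike-in than ins+ cells. Deeper sequencing is argued against: with all cells at 100000 reads their median was 4204 genes, above the upper quartile of 2733.75 in ins+ cells of plate 3. A well with 1 ins+ and 1 sst1.1+ cell may explain the pattern: 0.0592% of 1689 expressed genes, tuba8l alone, were over 2 times higher than in each of the 3 other pools. By the same condition the shares were 0.237% and 0.888% for the ins+ pools of plates 3 and 4 and 4.44% for the sst1.1+ pool. A mixture with 42% sst1.1+ reads left a median absolute log2 residual of 0.22, against 0.32 between the ins+ pools. The 42% was picked as the weight of smallest residual over these same genes. The 0.32 was not fitted and came from the pools with fewest cells. A residual below it is therefore no support for wells with a pair of cells. In 200 simulated pairs of cells the medians were 4095.5 genes and 72.9 gene reads per spike-in read, near the 71.1 observed. A single cell that runs both programmes with more RNA stays open. Its values were not simulated, so these counts do not separate it from a pair.

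Some values differ from a plain mixture, though they exclude nothing. The weight of sst1.1+ cells that each gene alone would need was 56.8% for sst1.1, 45.6% for ins, 46.9% for dkk3b, 42.3% for nkx6.2, 36.6% for pyyb, 34.7% for EGFP, 25.02% for hspa5 and 91.7% for pcsk1. In 10 of 57 sst1.1+ ins+ cells (17.5%, exact binomial interval 8.75 to 29.9%) sst1.1 took under 5% of the reads, against 16 of 200 simulated pairs (8%). Imaging of the sorted cells or a marker of single cells would decide.

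Ins+ cells held gcga at medians of 405 and 447 CPM on plates 3 and 4. On plate 4, alpha-cell RNA spread over the whole plate is argued against by the sst1.1+ cells, whose median of 17.8 CPM was 3.97% of that of the ins+ cells. The gates lay mostly in different rows, so RNA spread within rows is not covered. Plate 3 cannot decide, because its other gate, sst1.1+ ins+ with a median of 279 CPM, carried the ins programme as well. Alpha cells sorted along are argued against by gcgb, the second glucagon gene: in 52 ins+ cells with few reads of other hormones its median was 0.546% of that of gcga, against 84.1% in 13 cells with over 5% of reads in gcga. This holds for most of these cells and not for all: gcgb was under 10% of gcga in 34 of the 52, which still had a median of 455 CPM of gcga, and over 25% in 12, where RNA of alpha cells and low expression of both genes cannot be told apart. Low expression of gcga with little gcgb, in the 34 cells, is a hypothesis that these values leave open, and reads shared between related genes were not tested.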
